A study of Mus musculus with 6 samples.

How the data were processed

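RNA-seq was done on W-EGFP cells, interstitial cells of the fetal testis taken from FLE-EGFP mice at stage E16.5. In FLE-EGFP mice a fetal Leydig enhancer of Nr5a1 drives the fluorescent protein EGFP. Per the labels, each sample of 10000 cells was kept for 1 hour with 0.5 µM SAG, a small molecule that activates the Hedgehog signal transducer Smoothened, or with the vehicle DMSO. There were 3 libraries per group, 6 in all. Per the labels' protocols, RNA was isolated with an RNeasy Micro kit and libraries were made with the strand-preserving NEBNext Ultra II Directional kit.

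Per the submitters' processing notes, Trim Galore 0.6.4, STAR, featureCounts 2.0.0 and edgeR (listed as 2.2.1) were used on mouse build GRCm38 (mm10). The annotation, the strand setting of the counting and any filter were not given in the sources used here. The authors deposited 1 table of 24505 rows by gene symbol and 6 columns of normalized expression. Its name calls the values CPM, but the column sums ran from 932712 to 1055620 and differ between libraries, so the values are treated here as a scaled signal. In each column 100% of the values were whole multiples of 1 step within a tolerance of 0.01, which gave back whole reads. The scaling was found from the values: TMM factors computed from those reads equalled the factors implied by the column sums. The table's name also holds the element "siRNA", and the column names of both groups carry "siCnt". The labels, with no mention of siRNA, do not explain these. Whether the cells of both groups had received a control siRNA before the treatment is not stated. The columns were matched to the samples by treatment and replicate number.

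The recovered reads per library were 25491259, 22789079 and 18486396 for DMSO replicates 1 to 3 and 8518849, 8804335 and 7694479 for SAG replicates 1 to 3. In DMSO replicates 1 to 3, 1 read corresponds to a signal of 0.0414, 0.0462 and 0.0564. Intervals on reads cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules. The table held 92 rows for synthetic spike-in RNAs. These name no gene and were left out of the tests after the table had been seen; they held at most 0.0157% of a library's reads. Of the 24413 other rows, 7160 were at 0 in every library and 23376 matched a symbol of GENCODE M21, which is on GRCm38 and gave the coordinates.

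Values were tested as log2(signal + 1) with limma 3.58.1 (linear model per gene, eBayes with trend) in R 4.3.3, with group as the only term, on 12550 genes with a mean signal of at least 1. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are SAG minus DMSO on the log2(signal + 1) scale, which understates the change of low genes; plain folds are ratios of mean signals. The list of core Hedgehog targets was also compared by an exact two-sided permutation test over the 6 libraries, which cannot go below p = 0.1. No source says that the replicates were separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

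The tests, gene lists and alternatives, except those named as later, were fixed before the data were examined. The lists covered Hedgehog core targets, wider Hedgehog targets, Hedgehog pathway components, fetal Leydig steroidogenesis, cholesterol synthesis, interstitial progenitors, Notch, Wnt, BMP and TGF-beta and cAMP-CREB targets. They also covered immediate early genes, heat shock, unfolded protein and amino acid stress, inflammatory cytokine and interferon responses, p53 targets, proliferation, glycolysis and hypoxia, and extracellular matrix. Further lists held markers of Sertoli, germ, endothelial, macrophage, erythroid, peritubular myoid with vascular smooth muscle, and surface epithelial cells, and mitochondrially encoded, ribosomal protein and replication-dependent histone genes. The 25 lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 25, and again with an estimated correlation and with fry. Named genes were Gli1, Ptch1, Hhip and Smo; those among the 10 called genes with the largest fold change in each direction whose groups did not overlap, predicted genes aside; up to 4 members of each list with the smallest p; and Nr5a1 and EGFP. Some genes that these rules select are not reported here. Other genes were chosen after their values were seen and are named so.

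The limma step was tested on simulated counts for the SAG against DMSO comparison, drawn for 12484 tested genes from the real means and library sizes. It recovered 21% of 100 genes changed 1.5-fold and 80.6% of 98 genes changed 2-fold, and 7.41% of its calls were false. Alternatives were other pseudocounts, filters and scalings, robust and trendless limma, a replicate block, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads, another threshold, and each library left out in turn. Alternatives added after seeing the data were scaling by library total, DMSO reads thinned to the mean depth of the SAG libraries, removal of length and GC trends, rescaling without Rn45s, and a minimum log2 fold change of 1.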

Results

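Transcript levels were measured by RNA-seq in fetal testicular interstitial cells (W-EGFP cells, E16.5) exposed for 1 hour, per the labels, to the Smoothened agonist SAG or to the vehicle DMSO, with 3 libraries in each group. The comparison asked which transcripts differ when Hedgehog signalling is switched on at Smoothened in these cells. The deposited signal is CPM with scaling factors inside, as the authors made it, and errors after ± are SD over n = 3 libraries. The DMSO libraries held 18486396 to 25491259 reads and the SAG libraries 7694479 to 8804335, a depth ratio of 2.67 between the group means. The first principal component, with 66.4% of the variance, separated the groups. The second, with 20.8%, set SAG replicate 3 apart from SAG replicates 1 and 2. SAG replicate 3 also had 1.67% of its reads on the ribosomal RNA gene Rn45s, against 0.326% to 0.360% in the other 5 libraries, and 1205 spike-in reads, against 111 and 54 in SAG replicates 1 and 2 and 0 in DMSO.

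Core Hedgehog target genes rose with SAG. Gli1, the transcription factor that the pathway induces, rose from a signal of 0.625 ± 0.270 to 36.6 ± 8.46, which is 58.6-fold (log2 fold change 4.52, SE 0.21; limma with Benjamini-Hochberg adjusted p = 4.1e-06). The Hedgehog receptor gene Ptch1 rose 2.90-fold, from 13.7 ± 2.28 to 39.6 ± 11.6 (log2 fold change 1.44, SE 0.22), and Hhip, which encodes a Hedgehog-binding inhibitor, rose from 0.390 ± 0.305 to 1.66 ± 0.229 (log2 fold change 0.96, SE 0.26). Smo, which encodes Smoothened itself, rose 1.25-fold, from 140 ± 9.22 to 176 ± 14.6.

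Gli1, Ptch1 and Hhip passed the limma test, over all genes and when adjusted over the list alone. The Benjamini-Hochberg adjusted p from limma was 0.00145 for Ptch1, 0.0209 for Hhip and 0.0417 for Smo. The mean over the list of core targets was higher in each SAG library than in each DMSO library, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries can give. As a list the core targets stood above other genes in camera (Benjamini-Hochberg adjusted p = 6.3e-04), with adjusted p = 0.42 with an estimated correlation. The limma call of Hhip was lost without DMSO replicate 1 (Benjamini-Hochberg adjusted p = 0.0963) or DMSO replicate 3 (0.0684), and without SAG replicate 1, 2 or 3 its mean signal was under the filter and it was not tested. The limma call of Smo was lost without any 1 of DMSO replicate 1, 2 or 3 or SAG replicate 1 or 2 (Benjamini-Hochberg adjusted p from 0.0582 to 0.186). It was also lost with limma without trend (0.0817), with a replicate block (0.0613) and with length and GC trends removed (0.146), which moved its log2 fold change from 0.32 to 0.18.

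On GRCm38, Gli1 lies on chromosome 10 at 127329882 to 127341974 on the minus strand and Ptch1 on chromosome 13 at 63508328 to 63573598 on the minus strand. Hhip lies on chromosome 8 at 79965851 to 80058006 on the minus strand and Smo on chromosome 6 at 29735503 to 29761365 on the plus strand. The signal sums reads over each gene as the authors counted them.

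**Figure D1:**
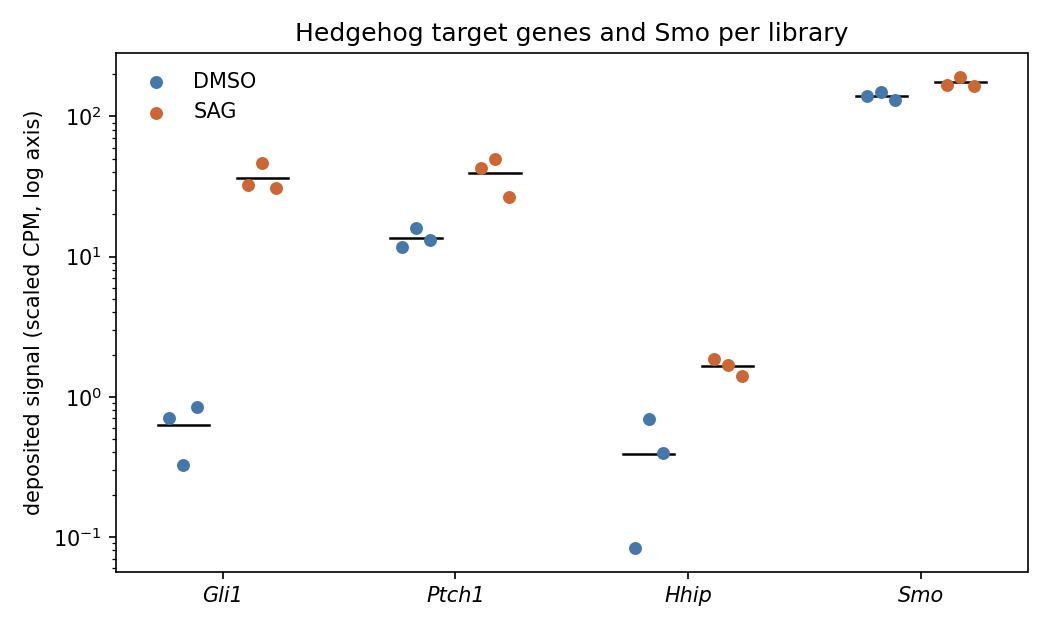
Deposited signal (scaled CPM, log axis) of Gli1, Ptch1, Hhip and Smo; each point is a library and each bar the mean of 3 libraries of a group. Gli1 lay between 30.8 and 46.3 in the SAG libraries and between 0.324 and 0.846 in the DMSO libraries.

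Over all genes, with Gli1, Ptch1, Hhip and Smo included, 1625 rose and 2084 fell among the 12550 tested (limma, Benjamini-Hochberg adjusted p under 0.05). After Gli1, the largest increases by fitted log2 fold change included those of Fgl2, Stc1 (stanniocalcin 1), Tgfbi, Fam180a, Ccdc3, Scube2 (a secreted protein that helps release Hedgehog ligands), Pard6b (a polarity protein) and Dpt (dermatopontin, a matrix protein). Fgl2 rose 28.2-fold, from 2.14 ± 1.32 to 60.3 ± 12.7, Stc1 rose 36.3-fold, from 0.774 ± 0.959 to 28.1 ± 8.43, and Tgfbi rose 30.9-fold, from 1.03 ± 0.425 to 31.9 ± 3.07. Ccdc3 had 0 reads in the 3 DMSO libraries, where 1 read is a signal of at most 0.0564. With SAG its signal was 13.3 ± 6.09, and no plain fold can be given. The other 4 rose by 15.5-fold (Pard6b) to 24.4-fold (Fam180a), with Scube2 going from 1.02 ± 0.826 to 22.0 ± 2.85. At such low DMSO signals single libraries moved the folds: with each library left out in turn Stc1 rose 24.7-fold to 122-fold, Scube2 17.2-fold to 40.5-fold, Dpt 14.6-fold to 34.2-fold and Pard6b 12.3-fold to 27.2-fold.

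The largest decreases included those of Rasgrp3 (a Ras activator), Scel (sciellin), Npnt (nephronectin, a matrix ligand of integrins), the chemokine gene Ccl17, Limch1, Ptgs2 (inducible cyclooxygenase), Flrt2, Ankrd1 and Galnt18. Rasgrp3 was 8.91-fold lower, at 27.8 ± 2.79 in DMSO and 3.12 ± 1.12 with SAG, and Scel was 30.9-fold lower, at 6.82 ± 1.47 and 0.221 ± 0.176 (24.7-fold to 57.2-fold with each library left out in turn). Npnt was 5.80-fold lower, at 81.7 ± 1.32 and 14.1 ± 3.78, and Ptgs2 4.41-fold lower, at 88.5 ± 12.0 and 20.1 ± 1.45. Ankrd1, the most abundant of these, went from 894 ± 64.2 to 216 ± 38.9 (log2 fold change -2.06, SE 0.13). For each gene named in this and the preceding paragraph as among the largest changes, the Benjamini-Hochberg adjusted p from limma was at most 1.23e-04 and no SAG library overlapped a DMSO library. A call in limma and groups that did not overlap were conditions for naming these genes.

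**Figure D2:**
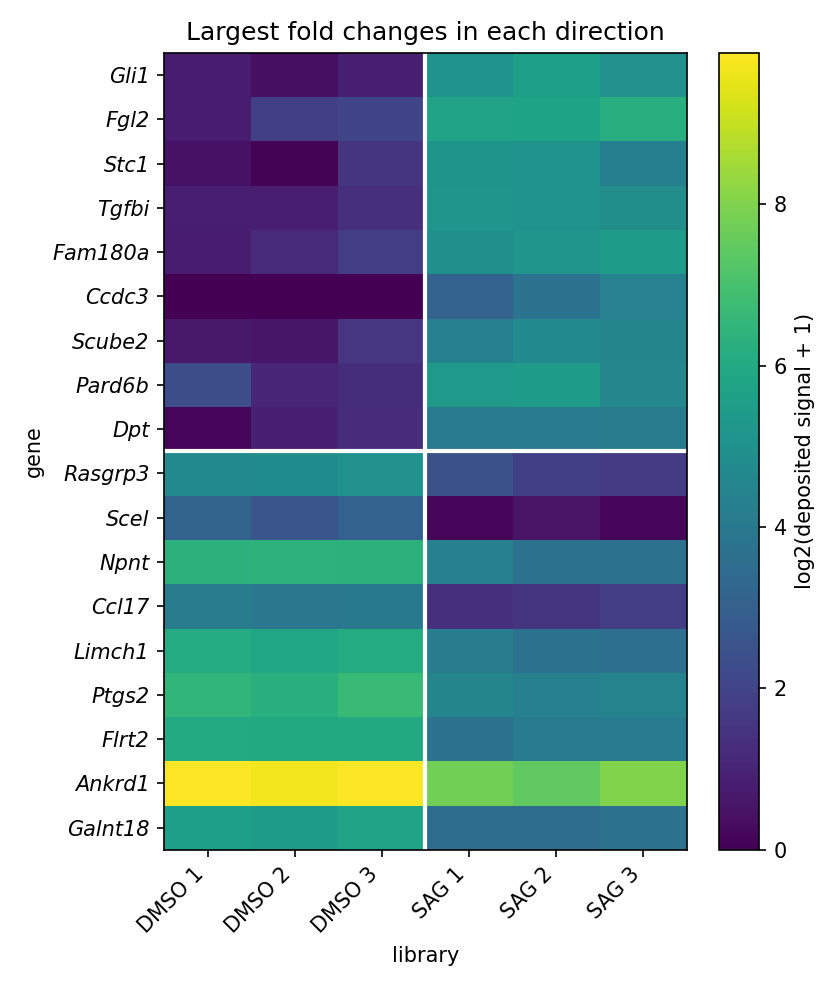
Log2(deposited signal + 1) of genes among the largest increases (upper block) and decreases (lower block), one column per library and one row per gene. Ccdc3 was at 0 in the 3 DMSO libraries and Ankrd1 was the most abundant, at 894 ± 64.2 in DMSO.

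Of the called genes, 466 rose and 320 fell by at least 1 on the log2 scale. The groups did not overlap for 48.0% of tested genes, against 10% by chance, and 5298 genes had an unadjusted p under 0.05 in limma. The calls were 43.8% higher genes with the deposited scaling and 66.3% when each library was scaled by its total alone, and the median log2 fold change of all genes moved from -0.03 to 0.10. The counts moved with single libraries: 930 higher and 1093 lower without DMSO replicate 1, 969 and 1136 without DMSO replicate 2, 901 and 1086 without DMSO replicate 3, and 2463 and 3373 without SAG replicate 3. Spread between replicates was unequal: the median absolute deviation of a gene from its group mean, in log2 units, was 0.0608 to 0.0627 in the DMSO libraries and 0.120, 0.145 and 0.197 in SAG replicates 1, 2 and 3.

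**Figure D3:**
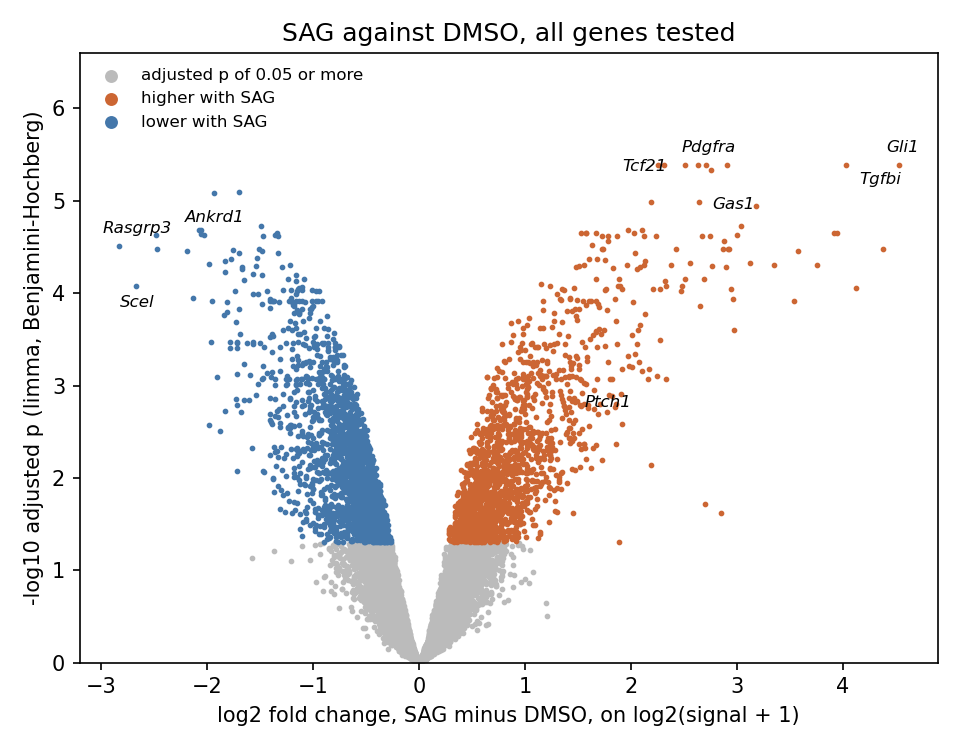
Log2 fold change (SAG minus DMSO, on log2(signal + 1)) against -log10 of the Benjamini-Hochberg adjusted p from limma, one point per tested gene; orange points rose, blue points fell and grey points did not pass. There are 1625 orange and 2084 blue points, and Gli1 has the largest fitted log2 fold change (4.52).

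Genes of cholesterol synthesis rose together. Of 24 measured genes 16 rose and 1 fell (17 and 1 when adjusted over the list alone), with a median log2 fold change of 0.65 (camera, Benjamini-Hochberg adjusted p = 8.0e-08; adjusted p = 0.13 with an estimated correlation). Insig1, a sterol sensor of the endoplasmic reticulum, rose 3.16-fold, from 42.7 ± 0.939 to 135 ± 17.4. Dhcr7, which encodes the last enzyme of a route to cholesterol, rose 2.30-fold, from 24.8 ± 2.41 to 57.1 ± 2.78. Hmgcs1 rose 1.88-fold, from 169 ± 1.41 to 316 ± 48.0, and Sqle 1.86-fold, from 70.6 ± 0.228 to 131 ± 9.25. The member that fell was Ggps1 (log2 fold change -0.56), named after its value was seen. With each library left out in turn it had 11 (without DMSO replicate 2) to 19 (without SAG replicate 3) higher and at most 1 lower.

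Genes of extracellular matrix moved in both directions, with more rising. Of 25 measured genes 8 rose and 4 fell (8 and 5 when adjusted over the list alone), with a median log2 fold change of 0.27 (camera, Benjamini-Hochberg adjusted p = 0.0152; adjusted p = 0.45 with an estimated correlation). The small proteoglycan gene Dcn rose 4.42-fold, from 22.4 ± 3.71 to 99.2 ± 3.51, and Fbln1 (fibulin 1) rose 3.53-fold, from 22.8 ± 2.80 to 80.3 ± 6.01. The collagen VI genes Col6a1 and Col6a2 rose 2.89-fold and 2.98-fold, Col6a1 from 340 ± 14.5 to 984 ± 82.9. Leaving out SAG replicate 3 gave 13 higher and 6 lower, and leaving out any other library 8 higher and 3 or 4 lower.

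Among genes of interstitial progenitor cells, 10 of 28 measured rose and 3 fell (11 and 6 when adjusted over the list alone). The receptor gene Pdgfra rose 6.34-fold, from 34.7 ± 2.36 to 220 ± 8.69, the transcription factor gene Tcf21 rose 5.82-fold, from 42.9 ± 3.36 to 249 ± 29.9, and the endothelin receptor gene Ednra rose 3.30-fold, from 19.9 ± 0.708 to 65.7 ± 3.15. The Notch ligand gene Jag1 was 2.58-fold lower, at 301 ± 13.1 in DMSO and 117 ± 2.92 with SAG. The list as a whole did not pass with all libraries (median log2 fold change 0.12; camera, Benjamini-Hochberg adjusted p = 0.054; adjusted p = 0.45 with an estimated correlation). At the preset correlation it passed without DMSO replicate 1 (camera, Benjamini-Hochberg adjusted p = 0.0253) and without SAG replicate 3 (0.00585), where 14 members rose and 5 fell. It also passed with a filter at a mean signal of 5 (0.0339), a replicate block (0.0386), thinned DMSO reads (0.0350) and length and GC trends removed (0.0227). It did not pass in the other settings tried for lists, without SAG replicate 2 for example (0.162).

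Markers of peritubular myoid and vascular smooth muscle cells fell. Of 13 measured genes 11 fell and 1 rose (12 and 1 when adjusted over the list alone), with a median log2 fold change of -0.58 (camera, Benjamini-Hochberg adjusted p = 3.5e-04; adjusted p = 0.45 with an estimated correlation). Acta2, smooth muscle actin, was 1.49-fold lower, at 9797 ± 133 in DMSO and 6581 ± 322 with SAG, and its limma call was lost without a filter on low values (Benjamini-Hochberg adjusted p = 0.0822). Actg2 was 1.95-fold lower, at 2128 ± 91.7 and 1089 ± 96.8, Cnn1 (calponin) 1.87-fold lower, at 686 ± 38.5 and 367 ± 87.6, and Lmod1 (leiomodin) 1.99-fold lower, at 513 ± 12.5 and 257 ± 58.6. Actins are near-identical in their coding parts, so their reads may be shared to a degree that the counting does not show. The member that rose was Abcc9 (log2 fold change 0.73), a channel subunit found in pericytes, named after its value was seen. The lower count was 7 without DMSO replicate 1, 2 or 3 and with scaling by library total, 8 and 11 without SAG replicates 1 and 2, and 12 of 12 measured without SAG replicate 3. Abcc9 was not among the calls without any 1 of the libraries except SAG replicate 1, with thinned DMSO reads, with a filter at a mean signal of 5 or with a replicate block.

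Ribosomal protein genes were lower as a list and unfolded protein and amino acid stress genes were higher. Of 78 ribosomal protein genes 23 fell and 2 rose (25 and 2 when adjusted over the list alone), with a median log2 fold change of -0.22 (camera, Benjamini-Hochberg adjusted p = 0.00101; adjusted p = 0.45 with an estimated correlation). With scaling by library total the list still passed, with a median of -0.08, 15 lower and 5 higher. Rpl39 was 2.27-fold lower, at 358 ± 18.9 and 157 ± 20.7, and Rps29 1.73-fold lower, at 369 ± 21.8 and 213 ± 23.1; both have many pseudogenes, so their reads are uncertain. Of 20 unfolded protein and amino acid stress genes 5 rose and 1 fell (5 and 1 when adjusted over the list alone), with a median of 0.23 (camera, Benjamini-Hochberg adjusted p = 0.0152, and 0.0516 without DMSO replicate 3; adjusted p = 0.45 with an estimated correlation). They were led by Trib3, a pseudokinase gene induced by ATF4, which rose 3.07-fold, from 12.1 ± 1.70 to 37.1 ± 13.5, while Herpud1 rose 1.59-fold and Sesn2 1.62-fold. Single libraries moved these counts: 12, 15 and 11 ribosomal protein genes fell without DMSO replicates 1, 2 and 3, and 27, 25 and 51 without SAG replicates 1, 2 and 3. The stress genes that rose were 4 (without DMSO replicate 3) to 8 (without SAG replicate 2), and those that fell 0 to 2.

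The wider Hedgehog lists were mixed. Of 26 wider Hedgehog targets 6 rose and 7 fell (6 and 8 when adjusted over the list alone), with a median of 0.07, a mean of -0.02 and a camera direction of down (Benjamini-Hochberg adjusted p = 0.957). Tbx2 rose 2.68-fold, from 54.5 ± 2.89 to 146 ± 26.2, while the cyclin genes Ccnd1 and Ccnd2 were 2.18-fold and 1.93-fold lower and Spp1 (osteopontin) was 4.25-fold lower, at 15.9 ± 1.31 and 3.74 ± 0.213. Of 36 pathway components 4 rose and 2 fell (2 and 1 when adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.339), with 14 and 6 without SAG replicate 3 and 2 and 0 without DMSO replicate 3. Scaling by library total gave 9 and 1. The co-receptor gene Gas1 rose 6.52-fold, from 26.0 ± 2.15 to 169 ± 32.8.

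In the fetal Leydig steroidogenesis list 5 of 15 measured genes rose and 0 fell (5 and 2 when adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.339). This list moved with SAG replicate 3: its median log2 fold change was 0.30 with all libraries and -0.20 without that library, where 5 rose and 5 fell. The higher count was 2 without DMSO replicate 1 or 3, 3 without DMSO replicate 2 or SAG replicate 2 (with 1 lower in the last) and 6 without SAG replicate 1, and 4 rose and 3 fell with length and GC trends removed. Hsd3b1, a steroid dehydrogenase gene with close paralogs, had signals of 3.73, 2.01 and 30.8 in SAG replicates 1 to 3 and of 0, 0.370 and 0.226 in DMSO. Its limma call was lost without DMSO replicate 1, 2 or 3 (Benjamini-Hochberg adjusted p = 0.0720, 0.0519 and 0.0602). Its reads in SAG replicates 1 to 3 (34, 19 and 240) ran alongside those of the adrenal gene Cyp21a1 (24, 17 and 275). List members under the filter, looked at after the results were seen, went the other way. Insl3 had 30, 11 and 2 reads in DMSO and 0, 1 and 2 with SAG, at lower depth. Cyp17a1 had 7, 4 and 0 reads in DMSO and 0, 0 and 0 with SAG. Inha, the inhibin alpha gene, rose 1.80-fold, from 11.5 ± 1.71 to 20.7 ± 3.38. Nr5a1, the master regulator of steroidogenic cells, was at 119 ± 4.08 and 104 ± 4.86 (limma, Benjamini-Hochberg adjusted p = 0.160), and EGFP at 98.9 ± 12.2 and 121 ± 11.7 (0.0961). Without SAG replicate 3 both passed, Nr5a1 lower and EGFP higher (limma, Benjamini-Hochberg adjusted p = 0.0344 and 0.0105). Nr5a1 also passed with length and GC trends removed (log2 fold change -0.39 against -0.19; 0.00723), and EGFP with scaling by library total (0.43 against 0.29; 0.0270), without globin genes (0.0270) and without Rn45s (0.0244).

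Signalling target lists held genes that changed in both directions, and none was called by camera. The fry test for 1 direction, which does not compare a list with other genes, passed 2 of them. These were the BMP and TGF-beta list (Benjamini-Hochberg adjusted p = 0.0170) and the cAMP-CREB list (0.0423), and not the Notch and Wnt lists (0.801 and 0.341). Over all tested genes 12.9% rose and 16.6% fell. Of 11 Notch genes 3 rose and 2 fell, of 10 Wnt genes 2 rose and 1 fell, of 18 BMP and TGF-beta genes 8 rose and 6 fell, and of 13 cAMP-CREB genes 3 rose and 1 fell. Adjusted over the list alone the counts were 3 and 2, 2 and 3, 8 and 6, and 3 and 1. Leaving out SAG replicate 3 gave 4 and 2, 3 and 3, 8 and 6, and 5 and 2, and leaving out DMSO replicate 1 gave 3 and 1, 2 and 1, 8 and 6, and 2 and 1. The camera Benjamini-Hochberg adjusted p ran from 0.372 to 0.860. The Notch list had a median of -0.03, which was above 0 with scaling by library total, and a mean of 0.04. Dtx4 rose 2.41-fold and Notch3 1.78-fold, and the Wnt feedback gene Nkd1 rose 2.92-fold while Axin2 was 1.90-fold lower. Atoh8 rose 2.18-fold while Ltbp2 was 2.02-fold lower, at 1508 ± 71.8 and 746 ± 63.7.

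Stress and early response genes were split. Of 37 immediate early genes 5 rose and 7 fell (6 and 10 when adjusted over the list alone), with Fos 3.02-fold higher, at 4.63 ± 0.329 and 14.0 ± 4.59, and Ctgf and Cyr61, both targets of YAP, 1.70-fold and 1.73-fold lower. This list had a median of -0.14, which was above 0 with scaling by library total, a mean of 0.01 and a camera direction of down (Benjamini-Hochberg adjusted p = 0.605). Its counts became 7 higher and 16 lower without SAG replicate 3; they were 4 and 5 without DMSO replicate 1, 2 or 3 and 7 and 6 with scaling by library total. Of 19 heat shock genes 2 rose and 4 fell (2 and 5 when adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.126, and 0.0312 without SAG replicate 3, where 3 rose and 11 fell). The near-identical Hspa1a and Hspa1b, whose reads cannot be told apart with certainty, were both 1.79-fold higher. Of 13 inflammatory cytokine response genes 2 rose and 3 fell (2 and 3 when adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.770), among them Socs3, 3.14-fold higher, and Lif, 3.30-fold lower. Of 8 interferon response genes 2 rose and 0 fell (3 and 0 when adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.215), with Stat2 1.83-fold higher.

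Lists of p53 targets, proliferation and glycolysis with hypoxia had median log2 fold changes of -0.28, -0.21 and -0.25 and did not pass as lists. Of 17 p53 targets 3 rose and 8 fell (4 and 8 when adjusted over the list alone), with Plk2 2.65-fold lower and Sesn1 2.15-fold higher. Of 30 proliferation genes 2 rose and 4 fell (1 and 3 when adjusted over the list alone), with Rrm2 2.38-fold lower, at 70.7 ± 3.95 and 29.7 ± 3.14. Of 17 glycolysis and hypoxia genes 2 rose and 6 fell (2 and 6 when adjusted over the list alone), with Hk2 1.76-fold lower. The camera Benjamini-Hochberg adjusted p was 0.175 for p53 targets, 0.175 for proliferation and 0.251 for glycolysis and hypoxia. The p53 list passed with length and GC trends removed (camera, Benjamini-Hochberg adjusted p = 0.0227; median -0.47, 3 higher and 10 lower). With scaling by library total the medians of these lists were -0.15, -0.08 and -0.11, with 4 higher and 7 lower, 4 and 3, and 2 and 4. Higher and lower genes without SAG replicate 3 were 4 and 9 for p53 targets, 2 and 10 for proliferation and 2 and 8 for glycolysis and hypoxia, and without DMSO replicate 1 they were 3 and 6, 0 and 3, and 2 and 4.

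Markers of other cell types were few at this filter. Of 7 Sertoli cell markers 0 rose and 1 fell, of 8 endothelial markers 1 rose and 2 fell, and of 7 surface epithelium markers 0 rose and 3 fell, with the same counts when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p from 0.215 to 0.884). The endothelial receptor gene Flt1 was 1.99-fold lower, at 89.1 ± 2.89 and 44.8 ± 10.5, while Sox18 was higher, at 0.361 ± 0.323 and 2.65 ± 0.368. Lower surface epithelium markers numbered 0 without DMSO replicate 1, 1 without DMSO replicate 3 or SAG replicate 1, 2 without DMSO replicate 2 or SAG replicate 2 and 3 without SAG replicate 3, and the endothelial list had 3 higher without SAG replicate 3 and 1 higher without any other library. The endothelial list had a median of 0.09, a mean of -0.01 and a camera direction of up. Of 6 histone genes 1 rose and 1 fell, also when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.339). The one that rose, H1f0, 1.51-fold higher, is a linker histone made outside replication. Germ cell, macrophage, erythroid and mitochondrially encoded lists had 2, 1, 0 and 0 measured genes and were not tested.

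**Figure D4:**
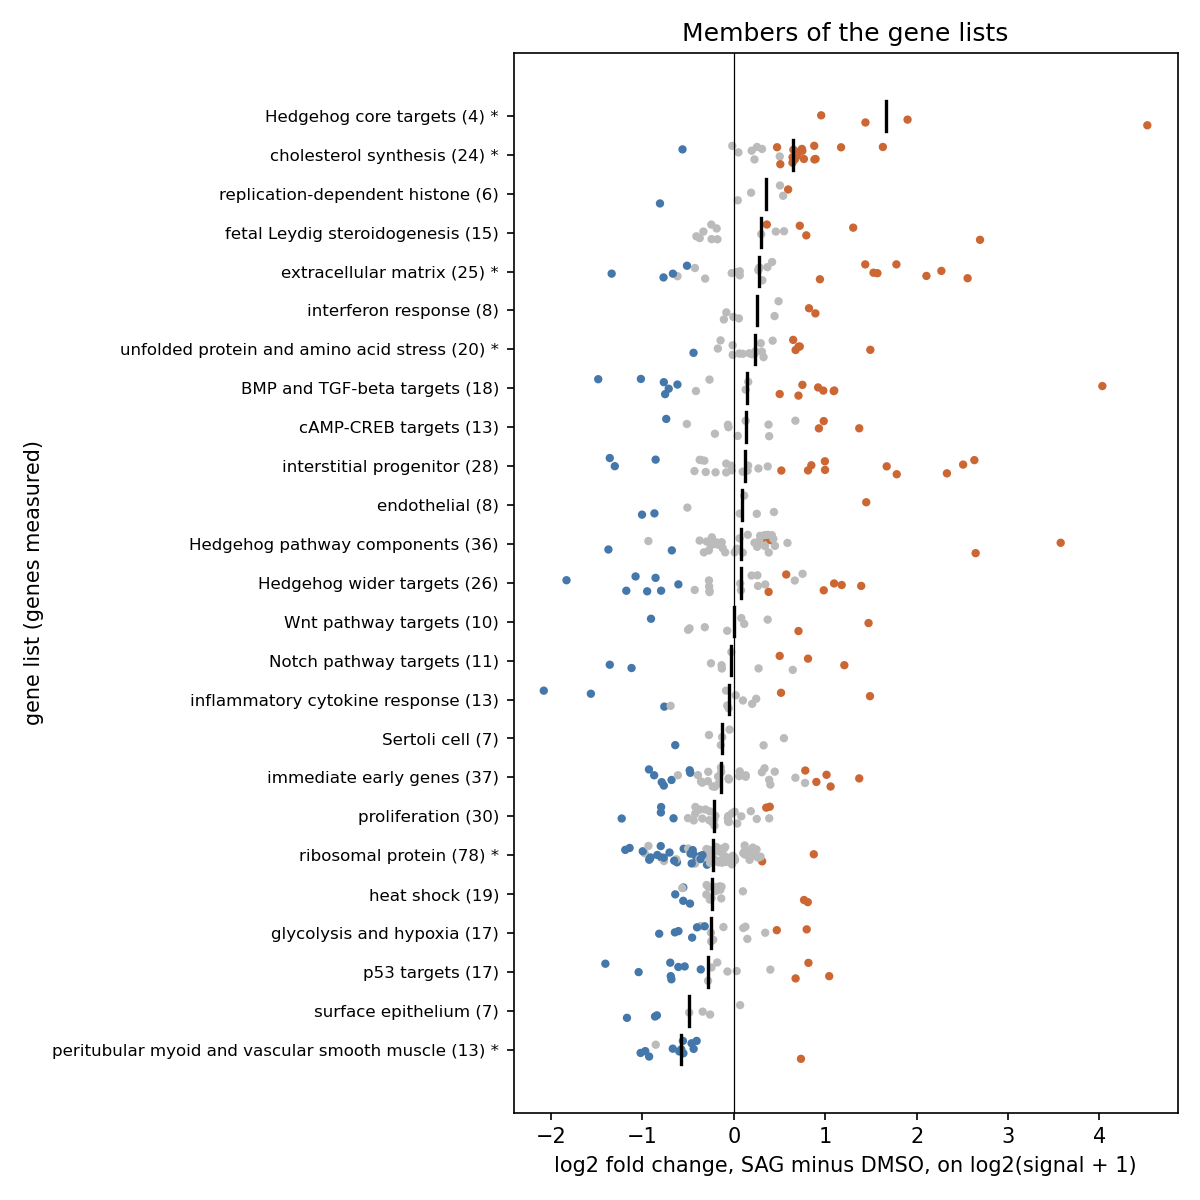
Log2 fold change (SAG minus DMSO, on log2(signal + 1)) of each measured member of the 25 tested lists, ordered by median; orange members rose, blue members fell, grey did not pass in limma, black bars are medians, and an asterisk marks lists past the camera threshold at the preset correlation. There are 6 such lists, 4 up and 2 down, and with an estimated correlation there are 0.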

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

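The tests of batches, of other splits and of the adrenal and spike-in transcripts were chosen after the results were seen; those of depth and of gene length and GC were fixed before their results.

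Synthetic spike-in RNAs, which no comparison uses, gave 111 reads in SAG replicate 1, 54 in SAG replicate 2 and 1205 in SAG replicate 3, and 0 in each DMSO library, which were deeper. They stand out as signal above the control samples in data outside the comparison. Of the 92 spike-in RNAs 30 had reads.

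SAG replicate 3 held these spike-ins together with transcripts of adrenal cortex genes: Cyp21a1, the adrenal 21-hydroxylase gene, had 0, 0 and 0 reads in DMSO and 24, 17 and 275 in SAG replicates 1 to 3. Mrap went the other way, with signals of 0.769, 0.636 and 0.514 in SAG replicates 1 to 3. The 6 adrenal genes together, Mrap among them, were 10.4 times (95% interval 8.55 to 12.7) as frequent in SAG replicate 3 as in SAG replicates 1 and 2. A response to SAG does not account for a difference of that size between libraries with the same treatment, and fetal Leydig cells of the testis are argued against by Cyp17a1, Insl3 and Lhcgr, with 2 reads in that library, whose upper bound is 0.922% of the 784 excess reads of 5 steroidogenic genes shared by both tissues. That bound was set after the values were seen, since the first one, a factor of 2 for the shared genes, was not reached (1.70). Of the shared genes Scarb1 held the most reads, and its signal was lower in SAG replicate 3 than in SAG replicates 1 and 2. The signals of Star, Cyp11a1, Hsd3b1 and Fdx1 were higher in SAG replicate 3. Reads or RNA from another library with adrenal RNA and spike-ins could not be told apart from other sources: the adrenal factor was 0.631 (95% interval 0.490 to 0.811) of the spike-in factor of 16.4, and 14.0 (95% interval 10.7 to 18.6) over the 3 adrenal genes with at most 3 DMSO reads, whose lack of baseline was noticed afterwards. Adrenal-like steroidogenic cells, which fetal testes can hold, also stay open as an untested explanation, since Cyp11b1 had 31, 45 and 29 reads in DMSO, though they would bring no spike-ins, and male cells would bring little Xist, an RNA of female cells, which had 0, 0 and 0 reads in DMSO and 1, 2 and 28 in SAG replicates 1 to 3.

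The size of the difference between the groups, 1625 higher and 2084 lower genes, was weighed against the 2.67-fold difference in depth, gene length and GC trends, and batches. Depth as the whole cause is argued against by thinning the DMSO reads to SAG depth, which kept 88.7% of the calls in the same direction. Length and GC trends as the whole cause are argued against by their removal, which kept 81.8%. Calls outside the 12083 genes with a known length and GC counted as lost there. A trend was present: over 5 classes of transcript length the median log2 fold change went from 0.03 (shortest) to -0.16 (longest). For SAG replicate 3 against the DMSO mean it went from 0.14 to -0.27. Separate library or sequencing batches of the groups stay open and cannot be told apart from the treatment. The 3 SAG libraries held 1370 spike-in reads and the 3 DMSO libraries 0, so whatever brought them split the libraries as the groups do. Replicate spread was also wider in the SAG libraries, in large part through SAG replicate 3. Log2 values correlated at 0.988 between SAG replicates 1 and 2, and at 0.970 and 0.966 between these and SAG replicate 3. Among DMSO libraries they correlated at 0.994 to 0.995. The part of the lower SAG depth in this spread was not tested. Only 1 of the 10 splits of the 6 libraries, the real one, gave as many genes in either direction, with 0 genes as the highest of the other splits, but 10 splits are too few for a share under 0.05. The other splits each mix DMSO with SAG libraries, so a group difference of any cause, a batch included, widens their spread. Their 0 genes thus cannot tell one cause from another. The treatment itself is the biological explanation that the design names, and it rests on the same contrast.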

How the results depend on the processing

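The alternatives chosen after seeing the data are scaling by library total, thinning, removal of length and GC trends, rescaling without Rn45s and the minimum log2 fold change; the others were planned. The mean log2 difference of the core Hedgehog targets stayed above 0 and past the camera threshold at the preset correlation in each alternative that gave a value, from 1.33 (pseudocount 5) to 3.12 (DESeq2). The numbers of higher and lower genes became 2477 and 1259 without globin genes, 2477 and 1260 with library totals and 2539 and 1256 without Rn45s. These 3 settings share a cause by construction: each sets every library to the same total and so drops the TMM factors. A minimum log2 fold change of 1 left 466 and 320. With each library left out in turn, higher genes ranged from 901 to 2463 and lower genes from 1086 to 3373, the lowest with a DMSO library left out and the highest without SAG replicate 3. Counts with edgeR (1709 and 2082) and DESeq2 (2138 and 1965) were within 1.5 times. No main call was called in the opposite direction in any setting. The 6 list calls became 0 with an estimated correlation, 17 with fry for 1 direction and 24 with fry for either direction. The last 2 do not compare a list with other genes. Among the called lists the estimated correlation ran from 0.0176 (cholesterol synthesis) to 0.199 (core targets), against the preset 0.01. For cholesterol synthesis the camera p went from 3.2e-09 to 0.0052, so the size of the correlation does not by itself account for that loss. Why the calls were lost was not tested.

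No pairing of the libraries by replicate number was seen: deviations of same-numbered libraries correlated at -0.02, 0.03 and 0.00. Not every library correlated best with its own number. The deviations of SAG replicate 3 correlated at -0.68 and -0.76 with those of SAG replicates 1 and 2. It thus dominated the SAG deviations, and a weaker pairing could go unseen. A replicate block gave 1549 higher and 1976 lower genes and 7 list calls, with Smo and Kif7 no longer called and the progenitor list called. Recomputed TMM factors equalled the deposited ones and moved nothing. Over 117 named genes and 2668 pairs of gene and alternative, 2570 kept direction and side of the threshold, 78 lost the call, 20 gained one and 0 reversed. In simulated data at this depth and n, 2-fold changes were mostly found (80.6%) and 1.5-fold changes mostly missed (21% found). That simulation changed only 100 genes by 1.5-fold and 98 by 2-fold. The real data gave far more calls, 1625 higher and 2084 lower, which loosens the adjusted threshold. The simulation also gave both groups the same spread per gene, apart from the effect of depth. In the real libraries the median absolute deviation from the group mean was 0.0608 to 0.0627 in DMSO and 0.120 to 0.197 in SAG. The simulated shares therefore need not hold for the real data.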

Other observations

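The tests of YAP, SRF and fibroblast genes were chosen after some of these genes had been seen among the changed ones; the test of gene span was fixed before its result, and the half-life values were added afterwards.

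Most measured targets of YAP and of SRF with its cofactor MRTF, some of them actin cytoskeleton genes, were lower with SAG. Actb, cytoplasmic beta actin, was at 6842 ± 188 in DMSO and 3886 ± 45.1 with SAG (log2 fold change -0.82, SE 0.10), Vcl (vinculin) had a log2 fold change of -1.13, Myh9 of -0.71 and Flna of -0.51, and the YAP targets Crim1 and Tgfb2 of -1.34 and -1.10. Others went the other way: Igfbp3 and Fhl2 rose (0.98 and 0.29), and Actg1, cytoplasmic gamma actin, was at 2092 ± 87.0 and 2499 ± 210 (limma, Benjamini-Hochberg adjusted p = 0.0961). A candidate explanation is lower activity of YAP and of SRF with MRTF. Of 22 measured YAP targets 15 fell and 1 rose, and the 21 not seen before the list was written had a median of -0.46 (camera p = 7.6e-05, Benjamini-Hochberg adjusted p = 1.1e-04 over 3 added lists; adjusted p = 0.12 with an estimated correlation). Of 20 measured SRF and MRTF targets 15 fell and 1 rose, and the 16 not seen before had a median of -0.63 (camera p = 2.2e-05, Benjamini-Hochberg adjusted p = 6.6e-05; adjusted p = 0.18 with an estimated correlation). Of these lists 3 and 7 genes also stand in the lists fixed before the data were examined, so the tests repeat part of the smooth muscle result, and a batch difference between the groups stays open for both.

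Fibroblast genes were higher: Dpt, Lum, Dcn, Cd34, Col15a1 and Pdgfra rose and Mfap5 fell among 7 measured genes of an adventitial fibroblast list, with Cd34 at a log2 fold change of 2.94 and Lum at 2.56. A shift towards a fibroblast-like profile may be read from this, but 4 of the 7 had been seen before the list was written and the other 3 had a median of 1.02 (camera, Benjamini-Hochberg adjusted p = 0.0593 over the added lists), too few to decide. Of the 7 genes 4 stand in the lists fixed before the data were examined.

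Genes with very long spans were among those that rose. RNA polymerase II moves a few kilobases per minute, so little full-length RNA of a gene over 300 kb can be made within the labelled 1 hour, and increases would then be rarer among such genes. Yet 21 of 310 genes over 300 kb rose by at least 1 on the log2 scale against 141 of 5084 genes of 20 to 100 kb, a ratio of 2.44 (95% interval 1.57 to 3.81). The reference class has the lowest share of rises, 2.77% against 4.37% up to 20 kb and 6.77% over 300 kb. Falls were also most frequent over 300 kb, 28 of 310 genes (9.03%) against 2.22% at 20 to 100 kb, so long genes changed more in both directions. Slit3, which spans 587 kb, went from 86.7 ± 6.56 to 281 ± 45.9. Rises were fewer than falls over 300 kb (21 against 28) and more numerous at 20 to 100 kb (141 against 113). The median signal was 16.1 over 300 kb and 30.9 at 20 to 100 kb. Since long genes changed more in both directions, the share of rises cannot decide how far new full-length transcription within 1 hour accounts for them. Reads from the first exons of unfinished transcripts, short isoforms and stabilised RNA stay open. A batch difference between the groups and a longer exposure than labelled stay open too. None of these could be tested. In the other direction, had all production stopped at the start, the fitted falls of Actb and Acta2 correspond to half-lives of 1.23 hours (95% interval 0.962 to 1.69) and 1.74 hours (95% interval 1.23 to 2.98).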
